A study of Mus musculus with 26 samples.

How the data were processed

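RNA-seq libraries came from mouse embryonic fibroblasts with floxed Brd4 and a tamoxifen-activated Cre, labelled WT or KO. Per the labels, deletion used 4 µM 4-hydroxytamoxifen for 96 h, starvation 0.05% serum for 72 h, and release complete medium with 10% serum. The labels do not say how WT cells were treated or which Brd4 exons were floxed. Per the labels, total RNA was made into libraries with the NuGEN Ovation kit and sequenced as paired ends on an Illumina HiSeq instrument. There were 26 libraries in 14 groups of genotype and time, 2 per group and 1 at 4 h.

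The deposited files hold raw read counts per gene, 1 library per file, and the unit matched the design. Per the file headers, the counts came from featureCounts 1.6.4 on STAR alignments to mm10 (STAR version not stated), with exons summed by gene in GENCODE vM20. Per the file headers, no option for pairs, strand or shared reads was set, so each mate counted by itself, strand was ignored, and reads with several positions or genes were left out. The deposited processing notes name Bowtie, edgeR and mm9 instead. The file headers were followed because they belong to the files used. Of 54752 genes in each file, 54723 IDs matched a symbol in the GENCODE vM21 annotation (GRCm38, ID version ignored). Symbols were shared by 203 IDs, and a shared symbol stands for the ID with the highest mean.

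Depth ran from 20487341 counts (KO 20 h replicate 2) to 66273720 (WT 16 h replicate 1), with 20728 to 25725 genes detected. Counts in the rRNA-like genes Gm26917 and Gm42418 made up 0.467 to 6.52% and mitochondrial genes 1.45 to 5.21%. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom of 50.0 to 448 over genes with at least 20 counts in the pair. Over all 325 pairs of libraries the lowest was 37.0, so no library was a second count of another. Intervals and floors cover counting error only.

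The main analysis was 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) of all 26 libraries with a coefficient per group, TMM scaling, and genes with CPM over 1 in at least 2 libraries (14915 genes). Tests were KO against WT in the mean over the 6 times with replicates and at each of these, each time against 0 h within a genotype, F-tests over the time course of each genotype, the genotype by time interaction, and the difference in release response at each time. P-values were adjusted by Benjamini-Hochberg over all genes, and called under 0.05. At 4 h CPM were compared with 95% Poisson intervals and no test. The design, the alternatives and the rule for naming genes were fixed before the data were examined.

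Fixed gene lists, 27 in number, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists. They covered immediate early genes, SRF and actin, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, ribosome biogenesis, G1 cyclins, BET and P-TEFb, interferon-stimulated genes, NF-kB, matrix, cholesterol and fatty acid synthesis, p53 targets, quiescence, oxidative phosphorylation, glycolysis and hypoxia, the unfolded protein and ATF4 response, and lysosome. The rest were markers of fibroblasts, macrophages, endothelium, epithelium, muscle, adipocytes, cartilage and bone, neural and erythroid cells. Members passing were counted over all genes and with adjustment over the list alone. At 4 h list medians were placed among 10000 random lists. Lists were described by log2(CPM + 0.5) averaged over members.

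Genes were named by rule: the 10 largest rises and 10 largest falls in the mean over times with adjusted p under 0.05, a mean CPM of at least 5 and the same sign at all 6 times, the 5 largest each way at each time, the 10 smallest p in F-tests, and up to 4 members per list by p. At 4 h they were the 3 largest ratios in the immediate early and G1 cyclin lists, and Myc was always named. Predicted genes were skipped, and exceptions are marked in the text.

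The pipeline was tested on simulated data with 14915 genes, 100 changed 2-fold and 100 changed 4-fold. In the KO mean edgeR recovered 88 and 100 with 9 false calls (DESeq2 1.42.0: 92, 100 and 32). At 16 h edgeR recovered 22 and 87 with 6 false calls (DESeq2 40, 93 and 28), and for WT 16 h against 0 h 27 and 86 with 6 (DESeq2 48, 94 and 38). For the WT time course it recovered 17 and 88 with 3 (DESeq2 52, 95 and 92), for the interaction 11 and 83 with 1 (DESeq2 44, 98 and 108), and for the difference at 16 h 1 and 52 with 1 (DESeq2 11, 72 and 32). Changes of 2-fold at a single time, and 2-fold differences in response, were thus mostly out of reach.

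Alternatives were DESeq2 size factors and total counts in place of TMM, no filter on low counts, DESeq2 tests, a replicate block, only the libraries of a time or genotype, each library left out in turn, and, added after the data were seen, leaving out the 3 libraries whose genotype or release score lay apart from their label. With those 3 left out 14823 genes were tested. The replicate block was same-numbered WT and KO libraries of a time for genotype tests, without the 4 h libraries, and replicate number within a genotype. No library was relabelled, and nothing else was left out. Scores for the closing tests are the mean log2(CPM + 0.5) of genes called higher minus that of genes called lower. The genotype score used genes called without the 4 and 8 h libraries. The release score used genes called in KO without the 4 and 12 h libraries, and was scaled to KO at 0 and 16 h.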

Results

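Brd4 encodes a bromodomain reader of acetylated chromatin that recruits the elongation kinase P-TEFb. Serum release of starved fibroblasts sets off immediate early genes, ribosome synthesis, S phase and mitosis in turn. Mouse embryonic fibroblasts labelled Brd4 wild type (WT) or knockout (KO) were starved, released, and profiled by RNA-seq at 0, 4, 8, 12, 16, 20 and 24 h. There were 2 libraries per genotype and time, except 1 each at 4 h, for 26 in all. WT and KO mean libraries so labelled, and levels are CPM (read counts scaled to library size) with TMM factors. Brackets after a gene give the log2 fold change, its standard error (SE) and the adjusted p. The labels do not say whether the 2 replicates of a group were separate cultures. The p-values thus measure only the spread between these samples, which may be technical. The main fit estimates each gene's spread from all groups together, so the calls at a time also depend on libraries of other times. For example, a fit of only the 4 libraries of 16 h called 2173 genes in place of 188. For 12 h such a fit called 0 in place of 211.

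Brd4 (ENSMUSG00000024002.17, chromosome 17, 32196274 to 32284722, GRCm38) was read at similar levels under both labels, at 81.0 ± 30.3 CPM in KO and 84.9 ± 23.8 CPM in WT (mean ± SD, n = 12 each). The mean log2 fold change of KO over WT was -0.08 (SE 0.15, adjusted p = 0.735 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was 0 (SE 0.17, adjusted p = 1) without the 3 libraries in doubt described next. Leaving out single libraries moved it between -0.21 (without KO 0 h replicate 2) and 0.01 (without WT 12 h replicate 1). By replicate, WT libraries held 56.7 and 74.6 CPM of Brd4 at 0 h, 87.3 at 4 h, 93.3 and 78.4 at 8 h, and 150 and 75.1 at 12 h. They held 75.3 and 101 CPM at 16 h, 69.1 and 94.3 at 20 h, and 81.1 and 70.2 at 24 h. KO libraries held 44.9 and 107 CPM of Brd4 at 0 h, 51.7 at 4 h, 84.0 and 164 at 8 h, and 79.3 and 83.1 at 12 h. They held 66.9 and 62.3 CPM at 16 h, 70.9 and 69.9 at 20 h, and 61.3 and 78.7 at 24 h. The deposited gene count sums all Brd4 exons, deleted or not, and unstranded counting leaves out reads shared with Gm4432 on the other strand, so it does not check the labels.

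In 3 libraries the label was in doubt, by scores from genes called at other times. On a score for genotype the library labelled WT 8 h replicate 1 stood at 0.89 (other WT libraries -0.92 to -0.11) and that labelled KO 8 h replicate 1 at -0.27 (other KO libraries 0.18 to 0.92). On a score for release the library labelled KO 12 h replicate 2 stood at 0.13, against 0.82 to 0.91 in the other 12 h libraries. Most libraries correlated best with a neighbouring time, so a best match outside the group did not by itself mark a library. The 8 h libraries, though, correlated best across genotypes (r = 0.74 and 0.70 over centred log2 CPM, against 0.31 and 0.26 within). The WT and KO 4 h libraries correlated best with 8 h replicate 2 of their own label (r = 0.67 and 0.70). KO 12 h replicate 2 correlated best with KO 0 h replicate 1 (r = 0.88, against -0.4 with its own replicate). All 26 libraries were kept as labelled. Leading counts are also given without these 3, a choice made after the data were seen.

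Averaged over the 6 times with replicates, KO fibroblasts expressed more of the neuropeptide Gal, the axon guidance ligand Sema7a and the transcription factor Mycn, and less of Igfbp5 and the cartilage matrix genes Col2a1 and Acan. Sema7a (chromosome 9, 57940112 to 57962865) stood at 160 ± 231 CPM in KO and 56.3 ± 143 CPM in WT (n = 12 each), and Mycn (chromosome 12, 12936093 to 12941914) at 12.4 ± 8.11 and 3.27 ± 6.55 CPM. All means here include the libraries in doubt as labelled, such as WT 8 h replicate 1 in WT. Igfbp5 (chromosome 1, 72857932 to 72874884) stood at 19.4 ± 25.9 CPM in KO and 145 ± 149 CPM in WT. Acan (chromosome 7, 79053483 to 79115099) stood at 36.9 ± 66.8 and 203 ± 85.5 CPM, and Col2a1 (chromosome 15, 97975602 to 98004695) at 20.7 ± 48.3 and 120 ± 83.0 CPM. Mycn is a relative of Myc, a classic BET-dependent oncogene. Myc itself was not called different, at 104 ± 45.7 CPM in KO and 101 ± 26.1 CPM in WT (log2 -0.03, SE 0.11, adjusted p = 0.883).

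By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3818 of 14915 genes differed between KO and WT in the mean over times, 1910 higher and 1908 lower in KO. Without the 3 libraries in doubt 6651 of 14823 differed, 3747 of them shared. The largest rises were in Gal (log2 5.80, SE 1.24, adjusted p = 0.00369), Sema7a (4.03, SE 0.60, 0.000467), Mycn (3.62, SE 0.43, 0.000131) and Olfm2 (2.57, SE 0.42, 0.000762). Fgl2 (2.49, SE 0.58, 0.00586), H2-DMa (2.43, SE 0.32, 0.000215), Dusp4 (2.36, SE 0.46, 0.00222), Elfn1 (2.00, SE 0.50, 0.00915) and Ccbe1 (1.88, SE 0.44, 0.00642) followed. The largest falls were in Igfbp5 (-3.70, SE 0.42, 0.000103), Col2a1 (-3.50, SE 0.52, 0.000471), Sfrp2 (-3.50, SE 0.57, 0.000715), Acan (-3.22, SE 0.42, 0.000218) and Capn6 (-3.09, SE 0.39, 0.000164). Then came Gprin3 (-3.04, SE 0.53, 0.00107), Megf6 (-3.03, SE 0.45, 0.000467), Penk (-2.91, SE 0.39, 0.000273), Tgfbi (-2.91, SE 0.35, 0.000135) and Eln (-2.80, SE 0.72, 0.0104). Larger by over 1.5 times in fold without the 3 libraries were the changes of Gal (7.07), Fgl2 (3.37), Dusp4 (2.96), Igfbp5 (-4.60), Col2a1 (-4.12), Sfrp2 (-4.80), Capn6 (-3.99), Gprin3 (-4.37), Megf6 (-3.71) and Eln (-4.23). Fgl2, Elfn1, Ccbe1, Sfrp2, Capn6, Megf6, Penk and Eln overlap other annotated genes, so their values are less certain in unstranded counts that drop shared reads. Hist2h3c2 also rose (2.76, SE 0.36, 0.000218), but has near-identical copies.

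**Figure D1:**
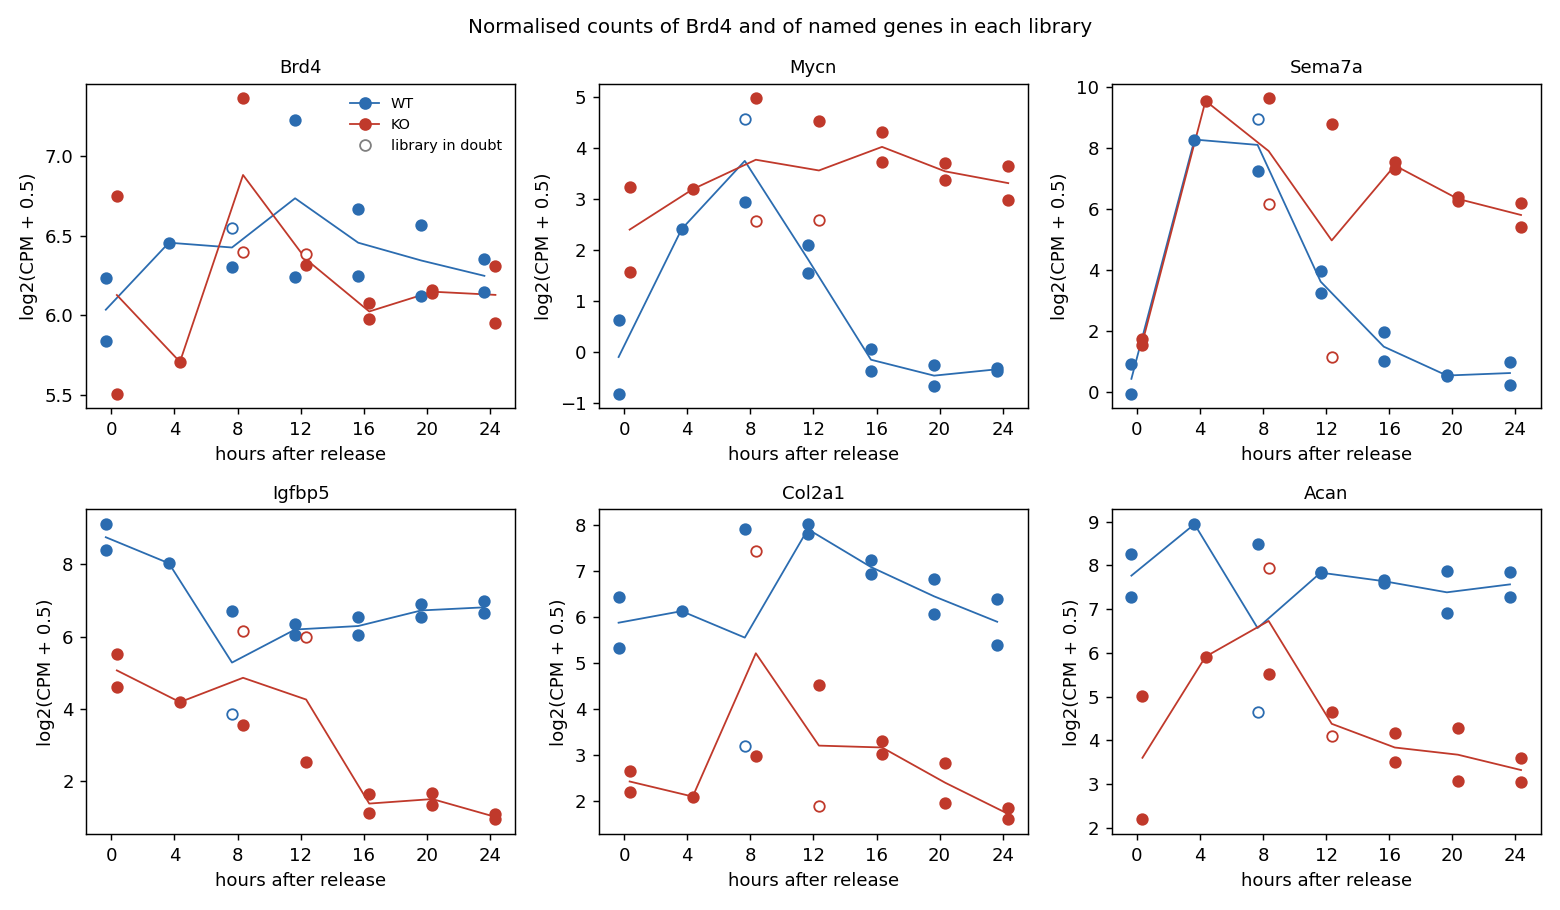
Expression of Brd4, Mycn, Sema7a, Igfbp5, Col2a1 and Acan as log2(CPM + 0.5) against hours after release, with a point for each library (blue WT, red KO, open for the libraries in doubt) and lines through the group means. At 24 h Acan stood at 9.69 CPM in KO and 193 CPM in WT.

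Mitotic genes formed the broadest difference in the mean over times: 36 of 39 G2/M genes fell in KO and 0 rose. Adjusted over the list alone 38 fell, as did 38 over all genes without the 3 libraries in doubt. The list median was -0.65 (camera adjusted p = 5.76e-23 with the preset correlation, adjusted p = 0.331 with an estimated correlation). At 24 h, though, the list stood higher in KO (median 0.36), so the mean joins times of unlike sign. Aurka (log2 -0.94, SE 0.12, adjusted p = 0.000164), Cdc25c (-0.81, SE 0.10, 0.000196), Plk1 (-0.80, SE 0.11, 0.000287) and Kif20a (-0.90, SE 0.13) led the fall. Immediate early genes, which serum and stress switch on within minutes, ran the other way: 14 of 24 rose and 0 fell (16 over the list alone, 15 without the 3 libraries). Their median was 0.73 (adjusted p = 2.69e-07, adjusted p = 0.331 with an estimated correlation). Ier3 (1.26, SE 0.16, 0.000164), Dusp1 (1.64, SE 0.25, 0.000514), Ccn2 (1.63, SE 0.25, 0.000558) and Klf2 (1.23, SE 0.20, 0.000713) led that rise.

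Lysosomal genes rose in KO, with 10 of 25 higher and 1 lower (14 and 1 over the list alone, 19 and 1 without the 3 libraries in doubt). The list median was 0.39 (camera adjusted p = 0.000159, adjusted p = 0.564 with an estimated correlation). Ctsz (log2 0.80, SE 0.18, adjusted p = 0.00496), Ctsd (0.89, SE 0.20, 0.00571), Hexa (1.00, SE 0.23, 0.0062) and Becn1 (0.30, SE 0.07) were the clearest. Matrix genes split 3 higher and 13 lower of 30 (5 and 15 over the list alone, 7 and 15 without the 3), with a median of -0.29 (adjusted p = 0.00248, adjusted p = 0.461 with an estimated correlation, and 0.0912 without the 3). Thbs2 (-1.82, SE 0.19, 8.74e-05), Col3a1 (-1.33, SE 0.19, 0.000311), Col6a2 (-0.90, SE 0.15) and Postn (-0.97, SE 0.16) were among the lower. Of 7 cartilage and bone genes 4 fell by either adjustment, with and without the 3 libraries. They were Acan, Col2a1, Col11a1 (-0.91, SE 0.18, 0.00259) and Alpl (-2.16, SE 0.49, 0.00494; -3.15 without the 3). The median of that list was -0.91 (adjusted p = 0.000989, adjusted p = 0.0706 with an estimated correlation).

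Unfolded protein and ATF4 targets fell in KO, 11 of 20 lower and 3 higher by either adjustment (13 and 3 without the 3 libraries). Their median was -0.53 (camera adjusted p = 0.00473, adjusted p = 0.754 with an estimated correlation). Xbp1 (log2 -0.59, SE 0.07, adjusted p = 0.000164), Asns (-0.83, SE 0.17), Ddit4 (-1.14, SE 0.24) and Mthfd2 (-0.78, SE 0.18) led. Ribosome biogenesis genes fell in 9 of 30 and rose in 0 by either adjustment, with a median of -0.14 (adjusted p = 0.0192, adjusted p = 0.873 with an estimated correlation). Gar1 (-0.45, SE 0.09, 0.00195), Dkc1, Ncl and Npm1 were first. Without the 3 libraries 3 rose, 13 fell and the list did not pass (adjusted p = 0.161). Interferon-stimulated genes fell in 3 of 21 and rose in 0 by either adjustment, with a median of -0.46 (adjusted p = 0.0171, adjusted p = 0.873 with an estimated correlation). These were Gbp2 (-1.78, SE 0.36, 0.00284), Xaf1 (-1.45, SE 0.39) and Irf9 (-0.43, SE 0.13).

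Several lists did not pass in the mean over times although single members did. G1/S and DNA replication genes had 1 higher and 2 lower of 49 (1 and 0 over the list alone), with a median of 0.06 (camera adjusted p = 0.786). E2f1 rose (log2 0.51, SE 0.11, adjusted p = 0.00406) and Cdca7 (-0.66, SE 0.19, 0.02) and Nasp (-0.63, SE 0.20, 0.0329) fell. Without the 3 libraries 2 were higher and 19 lower (median -0.12, adjusted p = 0.0299, adjusted p = 0.739 with an estimated correlation). Replication-dependent histones, whose near-identical copies make single genes uncertain, had 1 higher and 1 lower of 45 (1 and 0 over the list alone). Their median was -0.20 (adjusted p = 0.125), and 1 was higher and 19 lower without the 3. SRF and actin genes had 3 higher and 2 lower of 19 by either adjustment (median 0.17, adjusted p = 0.423). Tagln (1.25, SE 0.24, 0.00193) and Zyx (0.42, SE 0.09, 0.0029) rose, and Tgfb1i1 (-0.43, SE 0.09) and Lmod1 (-0.96, SE 0.27, 0.0161) fell.

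G1 cyclins, CDKs and inhibitors had 3 higher and 5 lower of 18 by either adjustment (median -0.16, camera adjusted p = 0.423). Ccnd3 (log2 0.36, SE 0.07, adjusted p = 0.00214) and Cdk6 (0.43, SE 0.11) rose, and Cdkn1a (-0.93, SE 0.19, 0.00279) and Cdkn1c (-1.08, SE 0.27) fell. BET and P-TEFb genes had 1 higher and 2 lower of 14 (2 and 3 over the list alone; median 0.04, mean -0.07, adjusted p = 0.786). The Brd4 paralog Brd2 rose (0.41, SE 0.11, 0.0121) and the P-TEFb inhibitors Hexim1 (-0.46, SE 0.09, 0.00205) and Hexim2 (-0.81, SE 0.16) fell. Quiescence genes had 3 higher and 5 lower of 19 by either adjustment (median -0.07, adjusted p = 0.423; 3 and 11 without the 3). Cited2 (0.55, SE 0.10, 0.0011) and Txnip (0.93, SE 0.19) rose, and Pdgfra (-1.30, SE 0.31) and Gas2 (-1.68, SE 0.41; -2.62 without the 3) fell.

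The p53 targets had 1 higher and 4 lower of 21 by either adjustment (median 0.06, mean -0.10, camera adjusted p = 0.53). Eda2r (log2 -1.40, SE 0.23, adjusted p = 0.000713), Sesn2 (-0.76, SE 0.17) and Bbc3 (-0.63, SE 0.17) fell beside Cdkn1a. Of 12 NF-kB genes 2 rose and 1 fell (4 and 3 over the list alone; median 0.29, adjusted p = 0.423). These were Csf1 (1.67, SE 0.29, 0.00101), Ptgs2 (0.55, SE 0.18) and Cxcl1 (-1.12, SE 0.34, 0.0231; -1.94 without the 3). Glycolysis and hypoxia genes had 1 higher and 3 lower of 21 (0 and 3 over the list alone; median -0.09, adjusted p = 0.423). Egln3 (-1.10, SE 0.22, 0.00269), Tpi1 (-0.42, SE 0.09) and Ankrd37 (-0.85, SE 0.27) fell and Pfkp rose (0.28, SE 0.10). In cholesterol and fatty acid synthesis Sc5d alone passed of 25 (0.72, SE 0.22, 0.0265; list median 0.16, adjusted p = 0.423). In oxidative phosphorylation Atp5b alone passed of 26 (-0.35, SE 0.10, 0.0164; list median -0.05, adjusted p = 0.449). Over the list alone 0 of either passed.

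Markers of fibroblasts and of other cell types were few and mixed. Of 11 fibroblast markers Pdpn rose (log2 1.25, SE 0.19, adjusted p = 0.000497) and Prrx1 (-0.83, SE 0.16) and Ly6a (-1.24, SE 0.26) fell (3 and 2 over the list alone; median 0.16, camera adjusted p = 0.786). Of 5 endothelial genes Flt1 (1.00, SE 0.26) and Kdr (1.32, SE 0.42) rose and Erg fell (-4.92, SE 0.77, 0.000675; -6.72 without the 3). That count was the same over the list alone (median 0.35, mean -0.57, adjusted p = 0.934). Of 3 macrophage genes Cd68 rose (0.98, SE 0.27, 0.0141), with 2 higher and 1 lower over the list alone (median 0.69, adjusted p = 0.53). Of 3 muscle genes Tnnt1 (-1.85, SE 0.33, 0.00119) and Chrna1 (-1.72, SE 0.51) fell (1 higher and 2 lower over the list alone; median -1.72, adjusted p = 0.251). Fabp4 fell among 4 adipocyte genes (-2.16, SE 0.40, 0.00163) and Nes rose among 5 neural genes (1.29, SE 0.38, 0.0215), each also over the list alone. The medians of these 2 lists were -0.31 (adjusted p = 0.251) and -0.13 (adjusted p = 0.786). Of 2 epithelial genes 0 passed by either adjustment (median -0.06, adjusted p = 0.796), and of the erythroid genes only Alas2 was measured (0.40, SE 0.28, adjusted p = 0.317).

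In starved cells, before release, 3 genes differed between KO and WT (n = 2 each) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, all higher in KO. They were Rcan2 (chromosome 17, 43801351 to 44039516; log2 2.77, SE 0.41, adjusted p = 0.0233), which restrains calcineurin, and the semaphorin receptor gene Plxna4 (chromosome 6, 32144268 to 32588192; 2.51, SE 0.35, 0.0133). The sulfatase gene Arsj (chromosome 3, 126363684 to 126440375; 1.41, SE 0.18, 0.0121) was the other. Igfbp5 stood at 34.6 ± 15.0 CPM in KO and 442 ± 154 CPM in WT, and Ccn3 at 905 ± 58.1 and 2511 ± 285 CPM, without passing. Unadjusted p lay under 0.05 for 1716 genes, DESeq2 called 320, and edgeR called 1013 without the 3 libraries in doubt and 0 in a fit of only the 4 libraries of 0 h. The count ran from 0 (without WT 0 h replicate 1 or KO 0 h replicate 2) to 26 (without KO 8 h replicate 1), and 9 of the 24 single omissions moved it past 1.5 times.

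No list member passed over all genes at 0 h. As wholes, the lists below passed with the preset correlation, but none of them did with an estimated correlation. The unfolded protein and ATF4 list was low in KO (median log2 -0.85, camera adjusted p = 5.22e-05, adjusted p = 0.634 with an estimated correlation), with 9 of 20 lower over the list alone. Cartilage and bone genes were low too, 4 of 7 over the list alone (-1.26, adjusted p = 0.00108, adjusted p = 0.0633 with an estimated correlation). So were ribosome biogenesis (-0.40, adjusted p = 9.36e-06) and G2/M genes (-0.50, adjusted p = 2.43e-06), each with adjusted p = 0.642 with an estimated correlation. Interferon-stimulated genes (-0.83, adjusted p = 0.00253, adjusted p = 0.649 with an estimated correlation) and G1/S genes (-0.32, adjusted p = 0.0021, adjusted p = 0.83 with an estimated correlation) also ran lower. Lysosomal genes (0.48, adjusted p = 5.22e-05, adjusted p = 0.634 with an estimated correlation) and immediate early genes (0.50, adjusted p = 0.0221, adjusted p = 0.649 with an estimated correlation) ran higher.

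At 4 h, when immediate early transcription fades and G1 genes start to be made, KO held more of the immediate early factors Maff, Junb and Ier3 than WT. It held less of the CDK inhibitors Cdkn1c and Cdkn1b and of Ccne2. Maff stood at 619 CPM (95% Poisson interval 610 to 627) in KO and 66.6 CPM (64.1 to 69.1) in WT, a log2 ratio of 3.21. Junb stood at 505 (497 to 513) and 122 (118 to 125) CPM (log2 2.05), and Ier3 at 296 (291 to 302) and 91.0 (88.1 to 93.9) CPM (1.70). Cdkn1c stood at 2.22 (1.75 to 2.79) CPM in KO and 9.02 (8.13 to 9.98) in WT (-1.81), and Cdkn1b at 15.9 (14.6 to 17.3) and 47.4 (45.4 to 49.6) CPM (-1.55). Ccne2 stood at 11.8 (10.7 to 13.0) and 32.2 (30.5 to 33.9) CPM (-1.41), and Myc at 117 (113 to 120) and 165 (162 to 169) CPM (-0.50). With n = 1 per genotype there is no replicate check and no test, and the intervals cover counting error only.

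Across lists at 4 h, each median was placed among 10000 random lists of the same size, in percentiles. Random lists do not share how members of a list move together, and n = 1 per genotype. The percentiles therefore describe these 2 libraries and do not measure an effect of genotype. Lysosomal genes (median log2 0.78, percentile 100), immediate early genes (0.69, 100), histones (0.66, 100), oxidative phosphorylation (0.37, 99.5) and SRF genes (0.38, 99.1) lay at the upper end. Cartilage and bone (-1.16, 0), G1/S (-0.65, 0), G2/M (-0.25, 0.13), ribosome biogenesis (-0.31, 0.16) and unfolded protein genes (-0.34, 0.18) lay at the lower end. Neural markers (0.57, 96.1), glycolysis (0.21, 88.0), endothelial markers (0.35, 87.5), NF-kB genes (0.23, 80.8) and interferon-stimulated genes (0.03, 66.4) lay between. So did fibroblast markers (0.09, 64.1), BET and P-TEFb genes (0.07, 62.9), p53 targets (0.06, 56.9) and cholesterol synthesis (-0.09, 15.3). G1 cyclins (-0.14, 11.4), matrix (-0.15, 3.49) and quiescence genes (-0.22, 3.3) sat lower.

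At 8 h, in mid G1, neither S phase nor growth genes were called different between the groups as labelled, and of the G1/S list Prim2 had the smallest p (log2 -0.26, SE 0.23, adjusted p = 1). The groups held the libraries labelled WT 8 h replicate 1 and KO 8 h replicate 1, each on the other genotype's side. The edgeR quasi-likelihood test called 0 genes, with unadjusted p under 0.05 for 90 and 1 call by DESeq2, and no list passed. Without the 3 libraries in doubt it called 741 genes, with 1 library per 8 h group assumed to vary like the other groups. In that set 36 of 49 G1/S genes fell in KO and 0 rose (43 over the list alone). Their median was -1.44 (camera adjusted p = 7.76e-54, still 0.0183 with an estimated correlation). The replication genes Dscc1 (-1.51, adjusted p = 0.0271) and Lig1 (-1.23, 0.0422) fell, while the elongation factor gene Aff1 rose (1.64, 0.00116).

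At 12 h, when WT cells were at their peak of G1/S transcripts, KO cells held fewer histone, G1/S and mitotic transcripts and more immediate early transcripts. The linker histone gene Hist1h1b (chromosome 13, 21779883 to 21780625) stood at 61.1 ± 21.5 CPM in KO and 403 ± 104 CPM in WT, and E2f7 at 17.6 ± 6.30 and 72.2 ± 3.76 CPM (n = 2 each). Ier3, a survival gene induced by serum, stood at 171 ± 49.1 CPM in KO and 36.1 ± 2.37 CPM in WT. The KO group here holds the library labelled KO 12 h replicate 2, whose profile resembled KO at 0 h. Without the 3 libraries in doubt the KO group is KO 12 h replicate 1 alone, assumed to vary like the other groups. Without KO 12 h replicate 1 the KO group is the library that resembled 0 h alone.

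The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 211 genes at 12 h, 65 higher and 146 lower in KO, and 1872 without the 3 libraries in doubt, but 0 in a fit of only the 4 libraries of 12 h. All 24 single omissions moved the count past 1.5 times, from 0 (without WT 12 h replicate 1 or KO 12 h replicate 2) to 2099 (without KO 12 h replicate 1). The largest rises were in Egr3 (log2 3.18, SE 0.72, adjusted p = 0.0476), Abat (2.75, SE 0.64, 0.0476), Egr2 (2.62, SE 0.61, 0.0476), Gas6 (2.47, SE 0.59, 0.048) and Inhbb (2.47, SE 0.54, 0.0443). Egr3 (1.13, adjusted p = 0.0788) and Egr2 (1.20, adjusted p = 0.0676) did not pass without the 3 libraries, and Abat (1.85) and Gas6 (1.86) were lower. The largest falls were in Tnfsf11 (-2.97, SE 0.68; -2.31 without the 3), Hist1h3g (-2.88, SE 0.63), Hist1h2bk (-2.85, SE 0.58, 0.0378), Hist1h2bm (-2.85, SE 0.61) and Hist1h1b (-2.72, SE 0.50, 0.0269).

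By list at 12 h, 21 of 45 histone genes fell and 0 rose (43 over the list alone, and 43 over all genes without the 3 libraries). Their median log2 was -2.20 (camera adjusted p = 8.64e-43, adjusted p = 0.135 with an estimated correlation). G2/M genes fell in 16 of 39 (37 over the list alone), with a median of -1.31 (adjusted p = 3.6e-34, adjusted p = 0.135 with an estimated correlation). Foxm1 (-1.30, SE 0.19, 0.025) and Aurkb (-1.91, SE 0.34, 0.025) were first. G1/S genes fell in 3 of 49 (45 over the list alone, 34 without the 3), with a median of -1.37 (adjusted p = 1.01e-28, adjusted p = 0.306 with an estimated correlation). These were E2f7 (-2.04, SE 0.33, 0.025), Tyms (-1.50, SE 0.27, 0.025) and E2f8 (-2.31, SE 0.50, 0.0433). Immediate early genes rose in 3 of 24 (19 over the list alone), Ier3 (2.24, SE 0.40, 0.025) beside Egr2 and Egr3. That list's median was 1.81 (adjusted p = 2.22e-11, adjusted p = 0.135 with an estimated correlation), and 0.86 without the 3. Ribosome biogenesis genes fell (-0.65, adjusted p = 8.59e-11), Gar1 alone over all genes (-0.98, SE 0.21, 0.0443) and 6 of 30 over the list alone, and lysosomal genes rose (0.81, adjusted p = 5.35e-06), 0 of 25 over all genes and 8 over the list alone. Both lists had adjusted p = 0.402 with an estimated correlation, and without the 3 the ribosome biogenesis median was -0.11 and did not pass (adjusted p = 0.273).

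**Figure D2:**
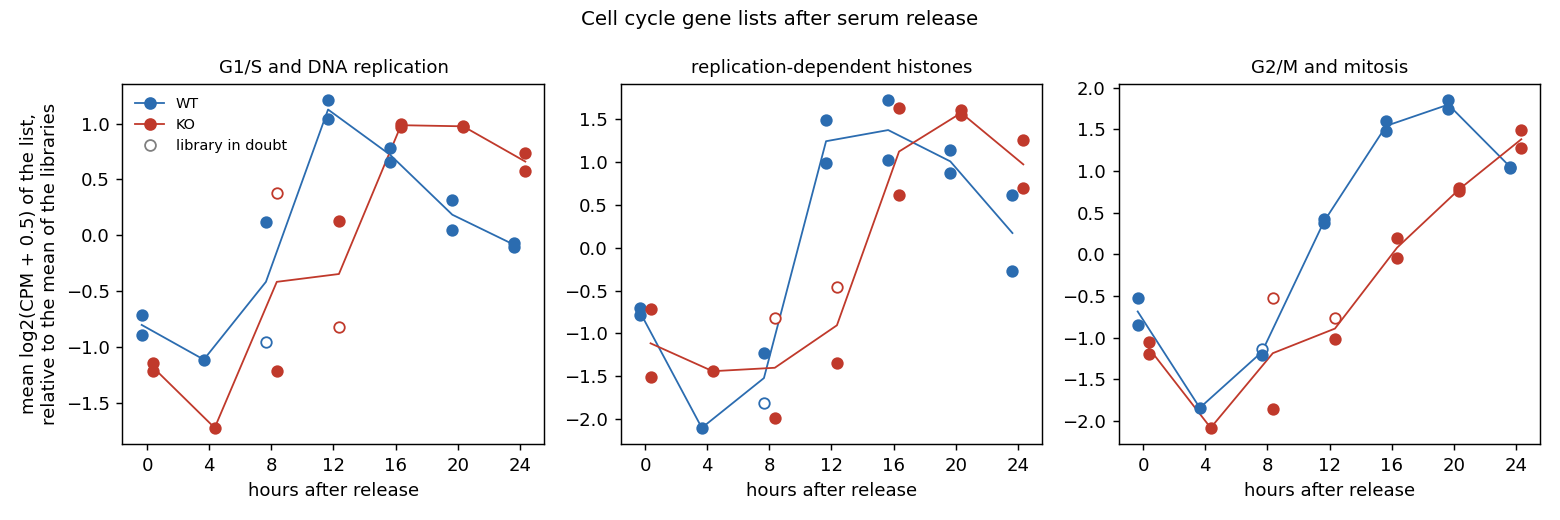
Mean log2(CPM + 0.5) of the G1/S and DNA replication, replication-dependent histone, and G2/M and mitosis lists, relative to the mean of the libraries, against hours after release. Points are libraries (blue WT, red KO, open for those in doubt) and lines join group means, with G2/M at 1.80 in WT and 0.78 in KO at 20 h.

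At 16 h KO cells lacked much of the mitotic program that WT cells had switched on, and kept the Mycn and Igfbp5 differences. Psrc1 (chromosome 3, 108383839 to 108388231), a spindle gene, stood at 1.08 ± 0.135 CPM in KO and 19.5 ± 3.33 CPM in WT, and Aurka at 31.6 ± 8.40 and 145 ± 12.1 CPM (n = 2 each). Mycn stood at 16.0 ± 4.61 CPM in KO and 0.409 ± 0.192 CPM in WT, and Igfbp5 at 2.16 ± 0.705 and 79.1 ± 20.0 CPM. The activin subunit gene Inhbb stood at 13.4 ± 1.72 CPM in KO and 1.53 ± 0.823 CPM in WT.

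The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 188 genes at 16 h, 61 higher and 127 lower in KO, and 2161 without the 3 libraries in doubt. Of the 24 single omissions 22 moved it past 1.5 times, from 0 (without KO 16 h replicate 1) to 866 (without KO 12 h replicate 1). The largest rises were in Mycn (log2 5.21, SE 1.12, adjusted p = 0.036), Inhbb (3.15, SE 0.55, 0.0138), Gdf11 (2.08, SE 0.35, 0.0125), Pdpn (2.03, SE 0.48, 0.0477) and Sync (1.91, SE 0.42, 0.0374). The largest falls were in Serpinb1a (-5.23, SE 0.91, 0.0137), Igfbp5 (-5.19, SE 1.10, 0.0339), Lrrc17 (-4.82, SE 1.12, 0.0471), Slc5a7 (-4.24, SE 0.89, 0.0333) and Psrc1 (-4.17, SE 0.54, 0.00224).

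G2/M genes at 16 h fell in 22 of 39 and rose in 0 (38 over the list alone, and 38 over all genes without the 3 libraries). Their median log2 was -1.38 (camera adjusted p = 2.2e-47, adjusted p = 0.0805 with an estimated correlation). Aurka (-2.20, SE 0.30, 0.00311), Plk1 (-1.92, SE 0.27, 0.0032), Cenpe (-2.11, SE 0.32, 0.00702) and Cdc25c (-1.64, SE 0.26, 0.00919) led. Immediate early genes rose (0.41, adjusted p = 0.00107), Ier3 alone over all genes (1.69, SE 0.39, 0.0471) and 7 of 24 over the list alone, as did lysosomal genes (0.55, adjusted p = 0.000417). Matrix genes fell (-0.59, adjusted p = 0.0354), Thbs2 alone over all genes (-2.03, SE 0.47, 0.0455) and 1 higher and 7 lower of 30 over the list alone. These 3 lists each had adjusted p = 0.663 with an estimated correlation, and the matrix list did not pass without the 3 (adjusted p = 0.113). The cartilage list fell with 0 of 7 past the threshold over all genes and 3 over the list alone (-1.16, adjusted p = 0.00842, adjusted p = 0.0805 with an estimated correlation). The quiescence gene Cited2 rose (1.16, SE 0.24, 0.0302).

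At 20 h the mitotic genes Cdc20 and Plk1 stood lower in KO than in WT. Cdc20, which activates the anaphase-promoting complex, stood at 54.5 ± 4.22 CPM in KO and 204 ± 2.40 CPM in WT. Plk1 stood at 29.8 ± 3.86 and 89.3 ± 2.76 CPM, and the matricellular gene Ccn3 at 88.5 ± 24.8 and 1176 ± 118 CPM (n = 2 each). The replication helicase gene Mcm6 stood at 289 ± 20.4 CPM in KO and 166 ± 12.3 CPM in WT, and Ccne2 at 122 ± 20.4 and 44.1 ± 9.18 CPM, but neither passed.

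The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 128 genes at 20 h, 46 higher and 82 lower in KO, and 2117 without the 3 libraries in doubt. Of the 24 single omissions 23 moved it past 1.5 times, from 0 (without WT 20 h replicate 1, KO 20 h replicate 1 or KO 20 h replicate 2) to 771 (without KO 12 h replicate 1). Rises were largest in Mycn (log2 5.55, SE 1.17, adjusted p = 0.0388), Inhbb (3.56, SE 0.56, 0.015), Fam20c (1.87, SE 0.36, 0.0304), Zdhhc24 (1.80, SE 0.37, 0.0348) and Eid3 (1.79, SE 0.35, 0.0304). Falls were largest in Igfbp5 (-5.50, SE 1.12, 0.034), Serpinb1a (-5.36, SE 0.89, 0.0159), Capn6 (-4.86, SE 1.04, 0.0397), Mylk (-3.84, SE 0.67, 0.016) and Ccn3 (-3.73, SE 0.53, 0.0128).

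G1/S genes at 20 h rose as a list (median log2 0.80, camera adjusted p = 9.74e-12, adjusted p = 0.698 with an estimated correlation). E2f1 passed over all genes (1.29, SE 0.27, 0.0397), 5 of 49 over the list alone, and 36 over all genes without the 3 libraries. G2/M genes fell in 6 of 39 (24 over the list alone, 33 without the 3), with a median of -0.91 (adjusted p = 2.57e-24, adjusted p = 0.44 with an estimated correlation). Cdc25c (-1.75, SE 0.26, 0.0128), Cdc20 (-1.91, SE 0.29, 0.0128), Plk1 (-1.58, SE 0.27, 0.0159) and Aurka (-1.57, SE 0.29, 0.0225) were first. Histones rose as a list (0.60, adjusted p = 6.57e-05, adjusted p = 0.859 with an estimated correlation), 0 of 45 by either adjustment. Immediate early genes rose too (0.48, adjusted p = 0.00108, adjusted p = 0.664 with an estimated correlation), 0 of 24 over all genes and 7 over the list alone. Matrix genes fell (-0.51, adjusted p = 0.00594, adjusted p = 0.594 with an estimated correlation), Thbs2 alone over all genes (-2.70, SE 0.48, 0.0193) and 6 of 30 over the list alone. The cartilage list fell (-1.41, adjusted p = 0.00594, adjusted p = 0.154 with an estimated correlation), 0 of 7 over all genes and 4 over the list alone.

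At 24 h the matrix genes Col3a1, Thbs2 and Acan stood lower in KO than in WT. Col3a1, a fibrillar collagen, stood at 438 ± 182 CPM in KO and 2895 ± 33.3 CPM in WT, and Thbs2 (chromosome 17, 14665500 to 14694235) at 38.1 ± 13.1 and 313 ± 92.6 CPM (n = 2 each). Acan stood at 9.69 ± 2.66 and 193 ± 52.3 CPM, and Igfbp5 at 1.53 ± 0.139 and 112 ± 18.4 CPM. Sema7a stood at 56.9 ± 21.0 CPM in KO and 1.08 ± 0.569 CPM in WT.

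The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 442 genes at 24 h, 179 higher and 263 lower in KO, and 2557 without the 3 libraries in doubt. Of the 24 single omissions 16 moved it past 1.5 times, from 1 (without WT 24 h replicate 2) to 1136 (without KO 12 h replicate 1). Rises were largest in Mycn (log2 5.05, SE 1.15, adjusted p = 0.0324), Nipal1 (4.84, SE 1.01, 0.0249), Olfm2 (4.50, SE 1.14, 0.0437), F2rl1 (3.34, SE 0.83, 0.0404) and Inhbb (3.33, SE 0.56, 0.0124). Falls were largest in Igfbp5 (-6.20, SE 1.15, 0.0186), Sfrp2 (-6.10, SE 1.57, 0.0456), Lrrc17 (-5.87, SE 1.16, 0.0217), Serpinb1a (-5.12, SE 0.87, 0.0126) and Capn6 (-4.88, SE 1.03, 0.0258).

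Matrix genes at 24 h fell in 7 of 30 and rose in 0 (10 and 1 over the list alone, 14 and 3 without the 3 libraries). Their median log2 was -0.92 (camera adjusted p = 8.74e-08, adjusted p = 0.0809 with an estimated correlation). Thbs2 (-3.04, SE 0.49, 0.0116), Col3a1 (-2.72, SE 0.48, 0.0128), Col6a2 (-1.79, SE 0.37, 0.0233) and Postn (-1.81, SE 0.40, 0.0291) led. Cartilage genes fell (-1.74, adjusted p = 0.00486, adjusted p = 0.0809 with an estimated correlation), Acan alone over all genes (-4.31) and 3 of 7 over the list alone. Adipocyte genes fell (-1.42, adjusted p = 0.013, adjusted p = 0.119 with an estimated correlation), 0 of 4 over all genes and 2 over the list alone. G1/S genes were higher in KO (0.74, adjusted p = 3.8e-09), Prim2 alone over all genes (1.11, SE 0.24, 0.0264) and 3 of 49 over the list alone, as were histones (0.73, adjusted p = 1.3e-07). Both had adjusted p = 0.827 with an estimated correlation, and G2/M genes were higher as well (0.36, adjusted p = 0.00366, adjusted p = 0.832 with an estimated correlation). The kinase gene Cdk6 rose (1.09, SE 0.27, 0.0395) and the inhibitor gene Cdkn2b fell (-1.35, SE 0.25, 0.0191). Xbp1 stood at 23.0 ± 2.04 CPM in KO and 63.3 ± 6.04 CPM in WT (-1.46), in a lower unfolded protein list (-0.39, adjusted p = 0.00339, adjusted p = 0.827 with an estimated correlation; 3 of 20 over the list alone).

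**Figure D3:**
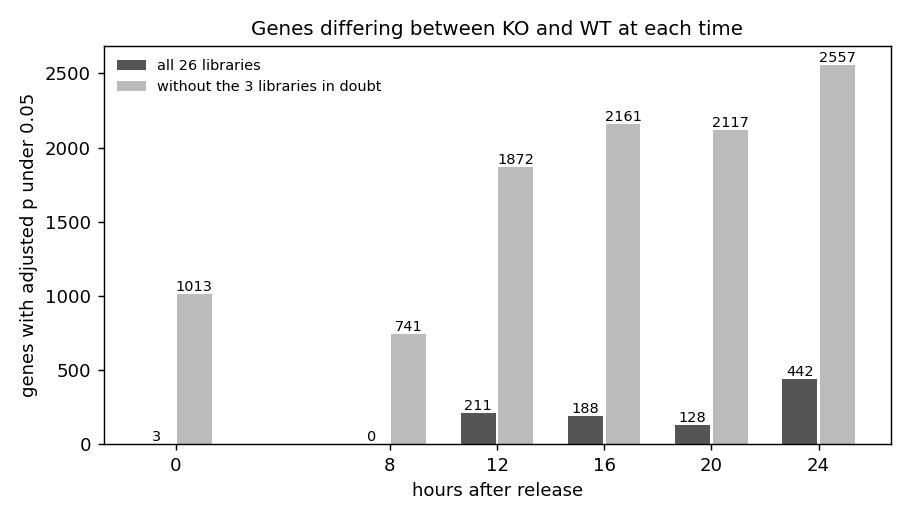
Number of genes with adjusted p under 0.05 in KO against WT at 0, 8, 12, 16, 20 and 24 h, as bars for all 26 libraries (dark) and without the 3 libraries in doubt (light). At 24 h the bars stood at 442 and 2557 genes.

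In WT cells serum release ran through growth, S phase and mitosis in order. The protease inhibitor gene Serpinb2 went from 0 counts at 0 h to 240 ± 238 CPM at 8 h, at least 7290-fold on a floor of 3 counts over the group (71.1 CPM and 2160-fold without WT 8 h replicate 1), and the BMP antagonist gene Grem2 from 0.196 to 71.9 ± 31.7 CPM (n = 2 each). The S phase gene Tyms went from 28.7 ± 3.09 CPM at 0 h to 100 ± 9.69 CPM at 12 h. Plk1 went from 13.3 ± 2.71 CPM at 0 h to 71.0 ± 8.49 at 16 h, 89.3 ± 2.76 at 20 h and 54.7 ± 7.66 CPM at 24 h. Fos stood at 820 ± 88.8 CPM at 0 h, already high for a gene that serum induces within minutes, and at 74.3 CPM at 4 h (n = 1).

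Over the WT time course 2947 genes changed by the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment (4620 without the 3 libraries in doubt, 4442 in a fit of only the WT libraries and 5081 by DESeq2). The smallest p-values belonged to the mitotic genes Cenpa, Plk1, Foxm1, Cep55, Gtse1, Kifc1, Cep128, Dlgap5, Aspm and Kif14 (adjusted p = 1.38e-05 each). Cenpa (chromosome 5, 30666777 to 30674830) went from 33.6 ± 6.09 CPM at 0 h to 181 ± 8.51 CPM at 20 h (n = 2). Omitting single libraries moved the count past 1.5 times in 3 cases: 1196 without WT 0 h replicate 1, 1347 without WT 0 h replicate 2 and 1700 without WT 8 h replicate 1.

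At 8 h against 0 h 3589 genes changed in WT (1759 up, 1830 down) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, in a group with the library labelled WT 8 h replicate 1, which resembled KO. There were 4356 without the 3 libraries in doubt, and single omissions, of which 3 moved it past 1.5 times, gave as few as 1158 (without WT 0 h replicate 1). After Serpinb2 the largest rises were in Grem2 (log2 8.61, SE 1.52, adjusted p = 0.0026), Gal (8.45, SE 2.71, 0.033; 2.88 and 0.049 without the 3), Sema7a (8.37, SE 1.77, 0.00482; 7.28 without the 3) and Ret (7.49, SE 1.42, 0.00312; 6.08 without the 3). The largest falls were in Bmf (-5.48, SE 1.19, 0.00539), Rtl3 (-5.26, SE 1.55; -4.42 without the 3), Chodl (-5.16, SE 1.47; -4.47 without the 3), Palmd (-4.76, SE 1.21) and Slc24a2 (-4.76, SE 1.18). Ribosome biogenesis genes rose in 23 of 30 (26 over the list alone), among them Rrp12 (2.04, SE 0.36, 0.00263) and Wdr12 (1.51, SE 0.27, 0.0026). Their median was 1.27 (camera adjusted p = 6.48e-14, adjusted p = 0.81 with an estimated correlation). SRF genes rose in 14 of 19 (16 over the list alone; median 1.26, adjusted p = 6.11e-08, adjusted p = 0.81 with an estimated correlation). Quiescence genes fell in 11 of 19 and rose in 3 by either adjustment (median -1.22, adjusted p = 0.00231, adjusted p = 0.81 with an estimated correlation). Interferon-stimulated genes fell in 7 of 21 (10 over the list alone; -1.64, adjusted p = 0.0002, adjusted p = 0.81 with an estimated correlation). Ccn2 (4.05, SE 0.69, 0.00244; 3.31 without the 3), Fosl1 (4.09, SE 0.80, 0.00358) and Timp1 (4.36, SE 0.92, 0.00474) rose while Cdkn1b (-1.78, SE 0.39, 0.00552) and Jun (-1.46, SE 0.36) fell.

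At 12 h against 0 h 2294 genes changed in WT (1436 up, 858 down; 4602 without the 3 libraries; 4 without WT 0 h replicate 1) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. G1/S genes rose in 46 of 49 (49 over the list alone), with E2f7 (log2 2.51, SE 0.33, 0.00259), Tyms (1.80, SE 0.27, 0.00321) and, of the cyclin list, Ccne2 (2.97, SE 0.60, 0.00741). Histones rose in 39 of 45 (45 over the list alone) and G2/M genes in 25 of 39 (29), with Foxm1 at 1.39 (SE 0.19, 0.00277). Immediate early genes fell in 13 of 24 and rose in 1 (14 and 2 over the list alone), with Egr3 (-3.40, SE 0.72), Atf3 (-3.05, SE 0.65) and Fos (-3.84, SE 0.94, 0.0149). The medians of these 4 lists were 1.92, 2.10, 1.20 and -1.39 (camera adjusted p = 3.88e-32, 2.83e-25, 1.96e-16 and 9.95e-06, each with adjusted p = 0.403 with an estimated correlation). Beside Serpinb2 (20.1 CPM, at least 612-fold on the same floor), U90926 (7.33, SE 1.46, 0.00714), Grem2 (7.19, SE 1.46, 0.00766), Siglecg (6.23, SE 1.43, 0.0119) and Slco2a1 (5.78, SE 1.57) rose most. Chodl (-5.95, SE 1.54, 0.0186), Steap4 (-5.00, SE 1.17, 0.013), Slc26a7 (-4.39, SE 0.84, 0.00598) and Btg2 (-3.99, SE 1.04) fell most beside Fos.

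Later in WT, 1354 genes changed at 16 h (903 up, 451 down; 3565 without the 3 libraries) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. There were 839 at 20 h (583 up, 256 down; 2694) and 335 at 24 h (224 up, 111 down; 2382). Single omissions moved these down to 229, 176 and 4 (each without WT 0 h replicate 1) and up to 2333 and 1177 at 16 and 24 h (without KO 12 h replicate 1) and 1496 at 20 h (without KO 12 h replicate 1 or KO 12 h replicate 2). Past 1.5 times they moved in 6, 6 and 10 of 24 cases. All 39 G2/M genes rose at 16 h (median log2 2.23, camera adjusted p = 5.41e-70, still 0.0374 with an estimated correlation) and at 20 h (2.47, adjusted p = 7.17e-99, still 0.00936). At 24 h 37 rose, and 39 over the list alone (1.73, adjusted p = 3.17e-63, adjusted p = 0.0542 with an estimated correlation). Plk1 rose by 2.42 (SE 0.28, 0.000163) at 16 h and 2.75 (SE 0.28, 5.42e-05) at 20 h, Prc1 by 2.48 (SE 0.26, 0.000117) and Foxm1 by 2.08 (SE 0.19, 7.05e-05) at 16 h, and Cdc20 by 2.25 (SE 0.29, 0.00217) at 24 h.

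G1/S genes in WT went from 27 risen at 16 h (42 over the list alone) to 9 at 20 h (14) and 1 at 24 h (1). Their medians were 1.67, 1.02 and 0.79 (camera adjusted p = 2.56e-24, 4.91e-13 and 6.26e-09, and adjusted p = 0.431, 0.49 and 0.615 with an estimated correlation). Histones went from 38 of 45 (45 over the list alone) to 21 (44) and 0 (0). Their medians were 2.28, 1.85 and 1.02 (adjusted p = 3.07e-32, 1.69e-26 and 2.22e-10, and adjusted p = 0.379, 0.396 and 0.537 with an estimated correlation). Glycolysis and hypoxia genes rose at 20 h in 7 of 21 (13 up and 1 down over the list alone; 0.91, adjusted p = 3.48e-06, adjusted p = 0.451 with an estimated correlation).

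Among single WT genes, U90926, Grem2, Siglecg, Fxyd5 (log2 5.02, SE 1.03, adjusted p = 0.00664) and Vgf (4.70, SE 1.17, 0.0208) rose most at 16 h by edgeR. Dlk1 (3.32, SE 0.73, 0.0142) joined the first 4 at 20 h. Has2 (3.26, SE 0.52, 0.0055), Dlk1 (3.21, SE 0.73, 0.0326), Mcub (3.01), Selenoh (2.88, SE 0.37, 0.00217) and Hmga1b, which has a near-identical copy (2.87), led at 24 h. Falls were largest in Chodl, Steap4, Slc26a7, Tcp11l2 (-3.51, SE 0.44, 0.000257) and Enpep (-3.48, SE 0.73) at 16 h. At 20 h they were largest in Slc26a7, Fras1 (-3.31, SE 0.50, 0.000785), Sema5b (-3.13, SE 0.57), Nr4a1 (-3.09, SE 0.86, 0.0462) and Nrk. At 24 h they were largest in Fras1 (-3.39, SE 0.50, 0.00332), Sema5b (-3.38, SE 0.58), Nrk (-3.08), Sema5a (-2.73, SE 0.31, 0.00103) and Slc22a23 (-2.65).

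In KO cells ribosome biogenesis, G1/S and G2/M genes also rose after release. Mitotic genes stood higher at 24 h than at 20 h, a step that was not tested. Plk1 went from 18.7 ± 0.617 CPM at 16 h to 29.8 ± 3.86 at 20 h and 57.4 ± 8.25 CPM at 24 h, and Cenpa from 22.0 ± 2.28 to 43.0 ± 2.98 and 102 ± 18.3 CPM (n = 2 each). Foxm1 (chromosome 6, 128362967 to 128376146), which drives mitotic transcription, went from 39.7 ± 6.71 CPM at 0 h to 174 ± 1.58 CPM at 24 h. Fos stood at 1213 ± 9.61 CPM at 0 h and 51.0 CPM at 4 h (n = 1).

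Over the KO time course 3631 genes changed by the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment (6608 without the 3 libraries in doubt, but 561 in a fit of only the KO libraries and 5546 by DESeq2). The smallest p-values were in Cep55 (adjusted p = 6.63e-06), Gen1 and Foxm1 (1.76e-05), Cenpm, Kif15 and Zwilch (2.42e-05), H2afx (2.75e-05), Prc1 and Dlgap5 (2.87e-05) and Rad54l (2.99e-05). Single omissions moved the count past 1.5 times in 2 cases, to 1551 without KO 0 h replicate 2 and 2107 without KO 0 h replicate 1. The highest value was 5316 without KO 12 h replicate 1.

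At 8 h against 0 h 3738 genes changed in KO (1995 up, 1743 down; 1532 without KO 0 h replicate 2) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with the library labelled KO 8 h replicate 1 in the group. Ribosome biogenesis genes rose in 29 of 30 (30 over the list alone; median log2 1.58, camera adjusted p = 7.25e-24, adjusted p = 0.503 with an estimated correlation). SRF genes rose in 12 of 19 (17 over the list alone; 1.40, adjusted p = 1.08e-07, adjusted p = 0.631 with an estimated correlation). G1/S genes rose in 13 of 49 by either adjustment (0.94, adjusted p = 2.53e-05, adjusted p = 0.99 with an estimated correlation), but without the 3 libraries 6 rose, 9 fell and the list did not pass (-0.17, adjusted p = 0.735). Quiescence genes fell in 10 of 19 and rose in 2 by either adjustment (-1.32, adjusted p = 0.000137, adjusted p = 0.631 with an estimated correlation). Myc rose (1.87, SE 0.29, 0.00137). The largest rises were in Serpinb2 (9.07, SE 2.09, 0.00721), Pkp1 (8.39, SE 1.45, 0.00164), Grem2 (8.17, SE 1.51, 0.00222), Fibcd1 (8.08, SE 1.73, 0.0045) and Il11 (8.01, SE 1.97, 0.00935). The largest falls were in Lars2 (-5.26, uncertain), Steap4 (-5.06, SE 1.19, 0.00731), Bmf (-4.89, SE 1.17), Mettl7a1 (-4.61, SE 0.76, 0.00144) and Ppp1r3c (-4.27). Larger by over 1.5 times in fold without the 3 libraries were the rises of Serpinb2 (9.87), Pkp1 (9.29), Fibcd1 (8.99) and Il11 (8.99) and the falls of Steap4 (-5.65), Ppp1r3c (-5.83) and Bmf, which had 0 counts in KO 8 h replicate 2.

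At 12 h against 0 h edgeR called 0 genes in KO, with unadjusted p under 0.05 for 1618 and 122 calls by DESeq2, in a group that holds the library labelled KO 12 h replicate 2. Without that library alone edgeR called 2224, and without all 3 in doubt 3441, among them Rrs1 (log2 1.58), Timp1 (4.54) and Ung (3.06). With all 26 libraries G1/S genes still rose as a list (median 0.92, camera adjusted p = 6.63e-19, adjusted p = 0.435 with an estimated correlation), though 0 members passed. Myc did not pass (1.04, SE 0.28, adjusted p = 0.324). Without KO 12 h replicate 2 the group is 1 library, assumed to vary like the other groups.

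From 16 h on, 3422 genes changed in KO at 16 h (2007 up, 1415 down), 3098 at 20 h (1841 up, 1257 down) and 3573 at 24 h (2042 up, 1531 down) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Single omissions moved these down to 934 and 773 (without KO 0 h replicate 2) and 1021 (without KO 24 h replicate 2), and up to 4352, 3984 and 4377 (without KO 12 h replicate 1), past 1.5 times in 4, 4 and 3 of 24 cases. G1/S genes rose in all 49 at 16 h (median log2 2.23, camera adjusted p = 1.48e-32, adjusted p = 0.33 with an estimated correlation). E2f7 (2.63, SE 0.34, 0.00153) and Ccne1 of the cyclin list (2.75, SE 0.47, 0.00228) rose at 16 h and Prim2 (2.11, SE 0.24, 0.00026) at 20 h. G2/M genes rose in 38 of 39 at 20 h (1.87, adjusted p = 7.46e-39, adjusted p = 0.268 with an estimated correlation) and 39 at 24 h (2.51, adjusted p = 5.1e-58, adjusted p = 0.0771 with an estimated correlation). Foxm1 rose by 1.44 (SE 0.19, 0.00153), 1.84 (SE 0.19, 0.000123) and 2.13 (SE 0.20, 5.31e-05) at the 3 times, and Plk1 by 2.71 (SE 0.28, 5.73e-05) at 24 h. Among matrix and quiescence genes, Col3a1 (-2.43, SE 0.47, 0.00249) and Ogn (-3.05, SE 0.47, 0.000564) fell at 24 h and Pik3ip1 at 16 h (-3.19, SE 0.52, 0.0022).

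Single KO genes with the largest rises at 16 h by edgeR were Gal (log2 8.45, SE 2.50, adjusted p = 0.024), Serpinb2 (8.37, SE 2.05, 0.0105), U90926 (7.04, SE 1.48, 0.00491), Grem2 (6.65) and Sema7a (6.04, SE 1.59, 0.0139). At 20 h Gal (7.38), Serpinb2 (7.01), U90926 (7.01), Grem2 (6.36) and Siglecg (5.41) rose most. At 24 h U90926 (7.59, SE 1.50, 0.00282), Gal (7.24, SE 2.43, 0.0406), Grem2 (6.60, SE 1.45), Serpinb2 (6.59) and Wincr1 (5.63, SE 0.93, 0.000878) did. The largest falls at 16 h were in Chodl, Ano5 (-6.25, SE 1.68, 0.015), Rtl3 (-6.23), Steap4 (-6.18, SE 1.28, 0.0046) and Scara5 (-6.00, SE 1.22, 0.00419). Chodl stood at 2.33 ± 2.18 CPM at 0 h, 0.0154 at 16 h and 0.0489 CPM at 20 h, the last 2 from 1 and 2 counts. Steap4 (-6.86, SE 1.34, 0.00308), Ano5 (-5.18), Scara5 (-5.00) and Ackr3 (-4.98) fell with it at 20 h. Eln (-7.01, SE 2.20, 0.0306), Steap4 (-6.09, SE 1.26, 0.0036), Scara5 (-5.96), Ano5 (-5.80) and Chodl (-5.58) fell most at 24 h.

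The replication fork gene Donson and the abscission gene Cep55 were among the genes whose course after release differed between KO and WT. Donson (chromosome 16, 91676808 to 91688770, overlapping Son and Atp5o) went from 41.9 ± 0.283 CPM at 12 h to 16.2 ± 1.27 CPM at 24 h in WT, and from 22.1 ± 5.98 to 45.8 ± 1.46 CPM in KO (n = 2 each). Cep55 went from 90.8 ± 7.19 CPM at 20 h to 47.8 ± 0.224 CPM at 24 h in WT, and from 69.1 ± 4.20 to 112 ± 23.1 CPM in KO. Ccn3 stood at 1561 ± 2.31 CPM in WT and 65.5 ± 40.1 CPM in KO at 24 h, and the histone demethylase gene Kdm5b at 123 ± 0.906 and 47.4 ± 8.13 CPM.

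The genotype by time interaction passed for 40 genes by the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, and for 681 without the 3 libraries in doubt. With same-numbered WT and KO libraries of a time as blocks it passed for 0 genes. In the main fit the smallest p-values belonged to Donson, Pif1, Cenpa, Gen1, Ccn3, Hyls1, Gas2l3 and Kdm5b (adjusted p = 0.0206 each) and Cep55 and Rad54l (0.0212). Pif1, a DNA helicase gene, stood at 54.4 ± 3.05 CPM in WT and 10.9 ± 2.01 CPM in KO at 20 h. Gen1 stood at 46.7 ± 0.790 CPM in WT and 34.4 ± 6.45 CPM in KO at 16 h, and at 19.1 ± 2.44 and 50.1 ± 3.68 CPM at 24 h. Of the 24 single omissions 23 moved the count past 1.5 times, from 0 (without WT 16 h replicate 1, among others) to 1087 (without KO 12 h replicate 1).

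Time by time, the release response (each time against 0 h) differed between genotypes for 1 gene at 16 h and at 24 h, Serpina3h, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Serpina3h (chromosome 12, 104247905 to 104253669) had log2 differences of -4.91 (SE 0.67, adjusted p = 0.0237) and -4.62 (SE 0.67, adjusted p = 0.0492). This secreted serpin lies among close relatives and had low counts, so its value is uncertain, and it was named after its values were seen. At 8, 12 and 20 h edgeR called 0, with unadjusted p under 0.05 for 945, 684 and 639 genes and 20, 14 and 14 calls by DESeq2. Without the 3 libraries in doubt the 5 counts were 25, 21, 133, 160 and 363.

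As lists, G1/S genes responded less in KO than in WT at 12 h (camera adjusted p = 7.06e-24, adjusted p = 0.347 with an estimated correlation) and more at 20 and 24 h (median differences in log2 of 1.10 and 1.22, adjusted p = 7.38e-28 and 1.32e-21). With an estimated correlation the later times had adjusted p = 0.427 and 0.386. G2/M genes responded less at 16 h (-0.99, adjusted p = 2.69e-28, adjusted p = 0.341 with an estimated correlation) and more at 24 h (0.80, adjusted p = 1.54e-15, adjusted p = 0.386 with an estimated correlation). Histones responded less at 12 h (-1.89, adjusted p = 1.22e-47, adjusted p = 0.278 with an estimated correlation) and more at 24 h (1.27, adjusted p = 3.68e-16, adjusted p = 0.401 with an estimated correlation). No member of these lists passed over all genes, and over the list alone 19 of 45 histones responded less at 12 h and 13 of 39 G2/M genes at 16 h. Of 130 list and time pairs tested 46 had adjusted p under 0.05, 32 of them also with the same sign without the 3 libraries in doubt, and 0 with an estimated correlation.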

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

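The tests of the 8 h labels, of the KO 12 h replicate 2 time and of the cell cycle order were chosen after the results were seen, but the splits of the libraries were planned. The gene and list results are differences between genotypes in the response to release, found by testing the difference itself, and the library scores and KO against WT values are named as such.

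Over the 5 times 40 genes differed in their response, and 0 with same-numbered WT and KO libraries of a time as blocks. Adjusted p by the edgeR quasi-likelihood test was 0.0206 for Donson, Pif1, Cenpa, Gen1, Ccn3, Hyls1, Gas2l3 and Kdm5b, and 0.0212 for Cep55 and Rad54l. Serpina3h differed by log2 -4.91 at 16 h and -4.62 at 24 h. No splits were run for these. For KO against WT in the mean over times, 1 of 100 splits of the libraries within time points, the real one, called as many as 3818 genes, and the highest other called 1980.

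The 8 h replicate 1 libraries lay on the other genotype's side. A genotype score from 2652 higher and 2592 lower genes put KO minus WT at -1.16 in this pair, against 0.75 to 1.49 in the other 11 same-numbered pairs. Exchanged labels predicted a value below 0 of that size, which this pair met. But the same score put these libraries in doubt, so it is no separate test of their labels. Of the other pairs, only 8 h replicate 2 (1.08) did not enter the choice of the score's genes. Lower depth does not account for KO 8 h replicate 1, which held 6.5 M more counts than KO 8 h replicate 2. WT 8 h replicate 1 held 0.57 of the counts of its replicate and scored 1.08 above it, while at the other 5 times the WT library with fewer counts (down to 0.43 of the other) scored at most 0.10 above. The labels of these libraries may be exchanged, but no file shows where, they were not changed, and no biological explanation was tested.

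KO 12 h replicate 2 lay near the starved cells, with a release score of 0.13 (0 for KO at 0 h, 1 for KO at 16 h, from 1925 higher and 1221 lower genes). It held 10.3 M more counts than KO 12 h replicate 1, so lower depth does not account for it. KO 12 h replicate 1 scored 0.82, so slower release in all KO cells does not either. A wrong time label or a dish that was not released could each give this value, and the data do not separate them.

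Cell cycle lists peaked later in KO than in WT. The 3 libraries in doubt enter only 8 and 12 h. Without them the differences in response at 12 h stayed below 0, at -0.65 for G1/S, -0.93 for G2/M and -2.37 for histones. KO at 12 h is then 1 library, KO 12 h replicate 1. With total counts the G2/M difference in response at 24 h was 0.82 (0.80 with TMM), so scaling did not make it. Against fewer cycling KO cells at every time, G1/S genes at 24 h were higher in KO against WT by 0.74, with list means of 0.66 ± 0.11 in KO and -0.08 ± 0.02 in WT (n = 2). The calls behind -0.65, 0.80 and 0.74 were lost with an estimated correlation (adjusted p = 0.159, 0.386 and 0.827). Later S phase and mitosis in KO had no test apart from the pattern itself (G2/M genes in KO against WT at 24 h: 0.36, adjusted p = 0.832 with an estimated correlation), and an effect of tamoxifen or Cre was not tested, so both stay open.

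Median differences in log2 response (KO minus WT, camera with the preset correlation) follow by list, and the 5 times share the 0 h libraries. G1/S genes gave 0.52 at 8 h (-1.05 without the 3 libraries in doubt), -1 at 12 h, 0.53 at 16 h, 1.10 at 20 h and 1.22 at 24 h. G2/M genes gave 0.59 at 8 h (-0.34 without the 3), -0.86, -0.99, -0.54 and 0.80 at the later times. Histones gave 0.66 at 8 h (-0.62 without the 3), -1.89 at 12 h, 0.99 at 20 h and 1.27 at 24 h. Ribosome biogenesis gave 0.48, -0.25 (0.23 without the 3), 0.48, 0.49 and 0.34. Interferon-stimulated genes gave 0.96 (-0.37 without KO 8 h replicate 1) and 0.55 at 8 and 12 h, and unfolded protein genes 1.15 (-0.18 without the 3) and 0.44 at 8 and 20 h. Lysosomal genes gave -0.64 and -0.39 at 8 and 24 h. Fibroblast markers gave -0.57, -0.36, -0.31 and -0.35 at 8, 12, 20 and 24 h, and cartilage genes 0.99 at 8 h. Immediate early genes gave 1.26 and G1 cyclins -0.43 at 12 h, and SRF genes 0.53 at 16 h.

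At 16, 20 and 24 h cholesterol synthesis gave 0.64, 0.70 and 0.63, but -0.11, -0.04 and -0.13 without WT 0 h replicate 2, and quiescence genes gave -0.62, -0.74 and -0.74. Epithelial genes (2 measured) gave 3.63 and 3.41 at 16 and 20 h (the latter -0.36 with no filter on low counts), glycolysis genes -0.37 (0.04 without WT 20 h replicate 1) and -0.35 at 20 and 24 h, adipocyte genes -1.53 and -2.16 at 20 and 24 h, and matrix genes -0.56 at 24 h. Of these 46 list results 0 passed with an estimated correlation in all 26 libraries, and 7 did in either set of libraries.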

How the results depend on the processing

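The settings without the 3 libraries in doubt, and both scalings at 4 h, were chosen after the results were seen. All counts are of genes called by edgeR unless DESeq2 is named.

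Without the 3 libraries in doubt 6651 genes differed in the mean over times, and 1013, 741, 1872, 2161, 2117 and 2557 at 0, 8, 12, 16, 20 and 24 h. The WT time course then held 4620 genes, the KO time course 6608 and the interaction 681. DESeq2 tests gave 320, 1, 1291, 989, 932 and 1299 genes at the 6 times, 5081 and 5546 in the WT and KO time courses, and 865 in the interaction. With no filter on low counts the 6 times held 642, 7, 1437, 1248, 1230 and 1476 genes and the interaction 1600. With total counts 0 h held 5, 12 h 70 and the interaction 15. DESeq2 size factors left every count within 1.5 times.

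Fits of only the 4 libraries of a time gave 0 genes at 0 and 12 h, 2173 at 16 h, 1313 at 20 h and 1303 at 24 h. Fits of only 1 genotype gave 4442 genes in the WT time course and 561 in the KO time course. With same-numbered WT and KO libraries of a time as blocks, and without the 4 h libraries, counts were 0, 4, 47, 6 and 187 at 0, 12, 16, 20 and 24 h. The interaction then held 0. Same-numbered WT and KO libraries deviated together at 5 of 6 times but not at 8 h. From 0 to 24 h their r was 0.56, -0.41, 0.36, 0.37, 0.65 and 0.68. They were not treated as pairs in the main fit. But 8 h holds libraries in doubt, so its negative r does not decide whether the numbers pair the samples.

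Leaving out each of 24 libraries in turn, with a lone library assumed to vary like the other groups, gave 0 to 26 genes at 0 h, 0 to 2099 at 12 h, 0 to 866 at 16 h, 0 to 771 at 20 h and 1 to 1136 at 24 h. The WT time course ran from 1196 to 4223, the KO time course from 1551 to 5316, and the interaction from 0 to 1087. The mean over times stayed between 2941 (without WT 8 h replicate 2) and 4925 (without KO 12 h replicate 2). At 4 h the immediate early median of 0.69 moved to 0.65 with DESeq2 size factors and 0.64 with total counts.

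Some list medians changed sign. In the mean over times G1/S went to -0.12 without the 3 libraries. For differences in response at 8 h, leaving out the 3 gave SRF 0.38, G1/S -1.05, G2/M -0.34, histones -0.62, G1 cyclins -0.22 and unfolded protein genes -0.18. Single omissions at 8 h ran from -0.37 to 0.41 for SRF, -0.56 to 1.32 for G1/S, -0.31 to 1.09 for G2/M, -0.19 to 1.22 for histones, -0.88 to 0.68 for immediate early genes, -0.37 to 1.37 for interferon-stimulated genes and -0.73 to 1.09 for cholesterol synthesis. At 12 h, leaving out the 3 gave ribosome biogenesis 0.23 and quiescence -0.39, and single omissions ran from -0.97 to 0.23, -0.39 to 0.68, and, for cholesterol synthesis, -0.54 to 0.89. At 16 h histones ran from -0.42 to 0.64 and cholesterol synthesis from -0.11 to 1.28. At 20 h cholesterol synthesis ran from -0.04 to 1.42 and glycolysis from -0.64 to 0.04, and the epithelial median was -0.36 with no filter. At 24 h cholesterol synthesis ran from -0.13 to 1.27.

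The genes with the largest rises and falls or the smallest p in each comparison, and Myc, were compared under each setting, but genes named only as list members were not. In the mean over times there were 21 (10 rises, 10 falls and Myc), 0 changed sign, and 18 kept their call under every setting. The other comparisons held 163 such results, with some genes in several. Of these 0 changed sign, 36 kept their call everywhere and 127 lost it in some setting, 51 of them under the replicate block, 13 in fits of the 4 libraries of a time, 11 with total counts and 2 without the 3 libraries in doubt. Over the 24 single omissions, calls among these 163 results were lost 784 times. Scaling shifted the median fold change of all genes by under 0.1 in log2.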

Other observations

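No test was added for these observations, which were picked after the results were seen and give group levels only. In WT cells G1/S genes were highest at 12 h, with Mcm6 at 365 ± 62.7 CPM and Ccne2 at 145 ± 75.3 CPM (mean ± SD, n = 2). In KO cells at 12 h they stood at 128 ± 53.1 and 29.7 ± 2.72 CPM, with the library labelled KO 12 h replicate 2 in the group. The mean of the G1/S list, relative to all libraries, reached 1.12 ± 0.12 in WT at 12 h and 0.98 ± 0.02 and 0.98 ± 0.01 in KO at 16 and 20 h. The G2/M list stood at 1.54, 1.80 and 1.05 in WT at 16, 20 and 24 h, and at 0.08, 0.78 and 1.38 in KO, where the last value was the highest of the course. Aurka, the mitotic kinase gene, went from 165 ± 6.44 CPM at 20 h to 92.9 ± 12.9 CPM at 24 h in WT, and from 55.6 ± 4.45 to 109 ± 3.44 CPM in KO.

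Several genes of the release response moved the same way under both labels. Grem2, which blocks BMP signalling, stood at 0.225 CPM at 0 h and 58.1 ± 19.5 CPM at 8 h in KO, beside 71.9 ± 31.7 CPM in WT. The noncoding RNA U90926 went from 0.188 CPM to 29.5 ± 9.23 CPM at 12 h in WT, and from 0.180 CPM to 30.0 ± 5.12 CPM at 24 h in KO. Steap4, a metalloreductase gene of starved cells, went from 27.5 ± 4.30 CPM to 0.846 ± 0.307 CPM at 12 h in WT, and from 21.2 ± 9.64 CPM to 0.305 ± 0.0648 CPM at 24 h in KO. Chodl, in contrast, started at 55.1 ± 20.6 CPM in WT and 2.33 ± 2.18 CPM in KO at 0 h.

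Brd4 read highest in 3 libraries, at 164 CPM in KO 8 h replicate 2, 150 CPM in WT 12 h replicate 1 and 107 CPM in KO 0 h replicate 2. These 3 also held the highest shares of the rRNA-like genes Gm26917 and Gm42418 (3.89, 6.52 and 4.61%). The high values may thus reflect library composition, which was not tested. An exon-level count would show whether the floxed exons are lost in the KO libraries, and in the library labelled WT 8 h replicate 1.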
